A study of Microtus ochrogaster with 51 samples.

How the data were processed

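Polyadenylated RNA from the nucleus accumbens of prairie voles (Microtus ochrogaster) was sequenced in bulk, 1 library per animal. The nucleus accumbens is a part of the ventral striatum that takes part in reward and in social attachment. Per the labels, each animal lived with a mate of the opposite sex. Animals were sampled after 2 weeks of pairing, after 2 weeks of pairing and 4 weeks of separation, or after 6 weeks of pairing. The 4 weeks are taken from the treatment label and the series design, and the treatment protocol gives no interval between separation and sampling. The labels also give each library a sex, a pair name shared by partners, and 1 of 4 cohorts. Groups were formed from treatment and sex. The pair number names a library within its group.

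The first deposited table holds normalized counts for 42 libraries, and the submitters' processing notes name DESeq2 and DESeq without a version. In that deposited table the signal of a gene is a read count divided by 1 size factor per library: all values (100.0%) of each column were whole multiples of 1 step, within a tolerance of 0.01 of a read. The reads behind the table were recovered from these steps, which gave 20067514 to 37737711 reads on genes per library (median 27487240). The second deposited table holds TPM (reads per gene length, scaled to the same total in each library) for 51 libraries. In it the authors' gene lengths differed between libraries, so no read totals could be recovered for the 9 libraries present in the TPM table only. Those 9 are the 6 libraries of 6-week pairs and 3 others. The aligner, counter, genome build and annotation release are not given in the sources used here. For 2 females of the 2-week group (replicates 9 and 15) the labels and the columns of the normalized table disagreed about which was included, and the columns were followed. The female partner of pair 23 was not analysed here.

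The tables list 23038 IDs of the form ENSMOCG and do not pair them with gene names. The reference gene table given for the species (26397 genes, assembly MicOch1.0) has no such IDs, and 0 of them matched. Genes are therefore given by ID only. The planned tests of 28 gene lists, the always-named genes and the adjustment for cell make-up scores could not be run. The rule for named genes was to take those past an adjusted p of 0.05 with the largest absolute log2 fold change, a mean normalized count of at least 100, a symbol, and the same sign in both sexes where sexes were averaged. Without symbols it was applied with its other conditions, to 2 genes per direction. Where fewer than 6 genes passed, those with the smallest p were named, again up to 2 per direction, without the abundance condition. ENSMOCG00000017273 and the IDs of the sex and cohort comparisons were reached in this way. ENSMOCG00000014170 was named outside the rule, after its values were seen.

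Comparisons in the normalized table used limma 3.58.1 (R 4.3.3) with eBayes trend and robust options on log2(normalized count + 1). Genes with a mean normalized count of at least 10 were kept, which left 14151. Treatment by sex group means were fitted and the Benjamini-Hochberg adjustment was used. Comparisons with 6-week pairs used limma on log2(TPM + 0.5) for genes with a mean TPM of at least 1, with sex and, within cohorts 3 and 4, cohort as terms. Fold changes are on these log scales, which understates the change of low genes. Cohorts 1 and 2 hold only 2-week pairs, and cohorts 3 and 4 only later groups, so no fit can hold both treatment and cohort in the comparison of separated with 2-week paired voles. Only separated and 6-week paired voles can be compared within cohorts.

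Partner similarity was the Pearson correlation across genes between the libraries of a female and a male, after subtraction of the mean of their cohort and sex. The mean over partners minus the mean over all non-partner combinations of the same cohort was tested by reassigning males within cohorts, one-sided. For the 9 pairs of the 2-week group all 10080 reassignments were enumerated instead of the 100000 planned resamples. For the 12 separated pairs 100000 resamples were drawn. Genes are not independent replicates, so these tests permute libraries and not genes.

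Partners share a pair number because the labels name them as a cohabiting pair, so the numbers pair the libraries by design. The partner correlation exceeded 0.1 in 6 of 9 2-week pairs, of which the 2 of cohort 1 share 1 value by construction, and in 10 of 12 separated pairs. The consensus correlation of partners over genes was 0.396, and 0.024 with the first principal component as a covariate. Fits with the pair as a replicate block are given beside a result where they changed it. No libraries were identical (0 pairs of libraries), and the lowest chi-square per degree of freedom between 2 libraries was 20.01, so all 42 were counted as separate.

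The comparisons, the gene lists, the rule for named genes and these alternatives were fixed before the data were examined: other pseudocounts and filters, quantile normalization, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the TPM table, cohort and replicate blocks, and leaving out cohorts or 6-week libraries. Removal of the first principal component of the centred values from partner similarity was among them. Alternatives chosen after seeing the data were the first principal component or the library measures as covariates, removal of the library measures or the trend with gene length from partner similarity, leaving out pairs or, for named genes, single libraries, and the TPM table without the 3 libraries the authors left out of the normalized table. The fragment index compares the reads per TPM of the shortest 5% and the longest 10% of 10084 genes in each library, and reflects how the length estimate of the authors differed between libraries. Each count of genes was also set against other splits of the libraries, 100 per comparison or 36 where no more exist, with partners kept together. For the sex comparisons and the interaction the sexes were exchanged within pairs. For separation in females or in males alone, the treatment labels of that sex only were reassigned, which parts partners.

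The fits were tested on simulated data in which 200 genes were changed by known folds. For separated against 2-week paired voles with sexes averaged (14151 genes), the fit recovered 86.4% of genes changed 2-fold, 66.7% of those changed 1.5-fold and 38.2% of those changed 1.25-fold. For males alone (14151 genes) these shares were 69.7%, 34.8% and 7.4%. For separation against 6-week pairing (12554 genes) the fit recovered 83.3% of genes changed 3-fold, 63.6% of those changed 2-fold and 30.9% of those changed 1.5-fold. These simulated libraries carried no component shared by partners or by many genes, so the shares may not hold for the real libraries. The partner test in 2-week pairs passed 0.05 in 1 of 20 simulations with no shared factor, in 10 of 20 where partners shared 0.5 of its variance and in 20 of 20 where they shared 0.9. Permutation tests and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.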

Results

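Gene expression in the nucleus accumbens was compared among 51 prairie voles to ask how a pair bond, its duration and the loss of a partner appear in the transcriptome of each sex. The TPM table covered 10 females and 10 males paired for 2 weeks, 12 females and 13 males paired for 2 weeks and then separated for 4 weeks, and 3 females and 3 males paired for 6 weeks. The normalized table covered 42 of them: 9 females and 9 males paired for 2 weeks, and 12 females and 12 males that had been separated. These 42 animals formed 21 complete pairs. The recovered reads per library were 28199583 ± 4816638 in 2-week paired females (SD, n = 9) and 28331032 ± 3178430 in 2-week paired males (SD, n = 9). They were 26699690 ± 3549965 in separated females (SD, n = 12) and 28431515 ± 4241714 in separated males (SD, n = 12). The 11 most abundant IDs took between 12.81% and 39.97% of the normalized counts of a library.

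Separation was first compared with 2 weeks of pairing, with sexes averaged. ENSMOCG00000019682 was higher after separation, with normalized counts of 565 ± 339 in separated females (SD, n = 12) against 158 ± 134 in paired females (SD, n = 9). In males the counts of this gene were 504 ± 218 (SD, n = 12) against 209 ± 169 (SD, n = 9). Its log2 fold change was 1.82 ± 0.30 (SE; limma adjusted p = 0.000697), and 12 of 12 separated females and 11 of 12 separated males lay above the mean of the paired animals of their sex. ENSMOCG00000003694 was also higher (log2 fold change 1.79 ± 0.33, SE; limma adjusted p = 0.00198), with 173 ± 152 normalized counts in separated females (SD, n = 12) and 38.8 ± 32.8 in paired females (SD, n = 9). Among lower genes with at least 100 normalized counts and the same sign in both sexes, those with the largest change were ENSMOCG00000018254 (log2 fold change -1.45 ± 0.25, SE; limma adjusted p = 0.000907) and ENSMOCG00000010003 (-1.44 ± 0.24, SE; limma adjusted p = 0.00087). ENSMOCG00000018254 had 1305 ± 645 normalized counts in paired females (SD, n = 9) and 304 ± 152 in separated females (SD, n = 12). ENSMOCG00000010003 had 4088 ± 2096 normalized counts in paired females (SD, n = 9) and 934 ± 467 in separated females (SD, n = 12). Both were below the paired mean in 12 of 12 separated females and 11 of 12 separated males. The mean of 2-week paired males was 793 ± 780 for ENSMOCG00000018254 and 2519 ± 2754 for ENSMOCG00000010003 (SD, n = 9). It rests in part on replicate 11, without which it was 538 ± 158 and 1632 ± 761 (SD, n = 8), with 11 of 12 separated males still below it for each. Of the genes below 100 normalized counts, ENSMOCG00000017273 had a larger fitted change (-2.70 ± 0.32, SE; limma adjusted p = 2.4e-06), which came from females alone and depends on the pseudocount.

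In all, 465 of 14151 genes passed an adjusted p of 0.05 with limma, 199 higher and 266 lower in separated voles. The changes were small: the median absolute log2 fold change of these genes was 0.42, and 313 of them changed by less than 1.5-fold. With the pair as a replicate block 8 genes passed, 2 higher and 6 lower. In that blocked fit ENSMOCG00000010003 kept its call (limma adjusted p = 0.0319), while ENSMOCG00000018254 and ENSMOCG00000019682 (adjusted p = 0.0516 for each) and ENSMOCG00000003694 (0.0643) did not, at the same fold changes. Treatment could not be told apart from cohort in this comparison. The count was 1898 with array weights (1071 higher and 827 lower, so more were higher there), 1246 with the first principal component as a covariate and 861 with read total and fragment index as covariates. It was 253 without cohort 1, 11 without cohort 2 and 7 without cohort 4, in fits with fewer libraries. Without cohort 2 the log2 fold changes of the named genes were 1.84 for ENSMOCG00000019682, 1.74 for ENSMOCG00000003694, -1.10 for ENSMOCG00000018254 and -1.17 for ENSMOCG00000010003, and none passed (adjusted p from 0.113 to 0.149). Without cohort 4 those of ENSMOCG00000019682 and ENSMOCG00000003694 were 1.65 and 1.66 and did not pass (0.228 for each, the highest over their alternatives). Their lowest adjusted p over the alternatives came from DESeq2, at 1.56e-05 for ENSMOCG00000019682, 6.21e-06 for ENSMOCG00000003694, 3.5e-07 for ENSMOCG00000018254 and 9.11e-08 for ENSMOCG00000010003. With 1 pair left out the count was 288 (pair 8), 236 (pair 16), 809 (pair 17), 269 (pair 25), 308 (pair 29) and 305 (pair 30). TPM values gave 39 genes.

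**Figure D1:**
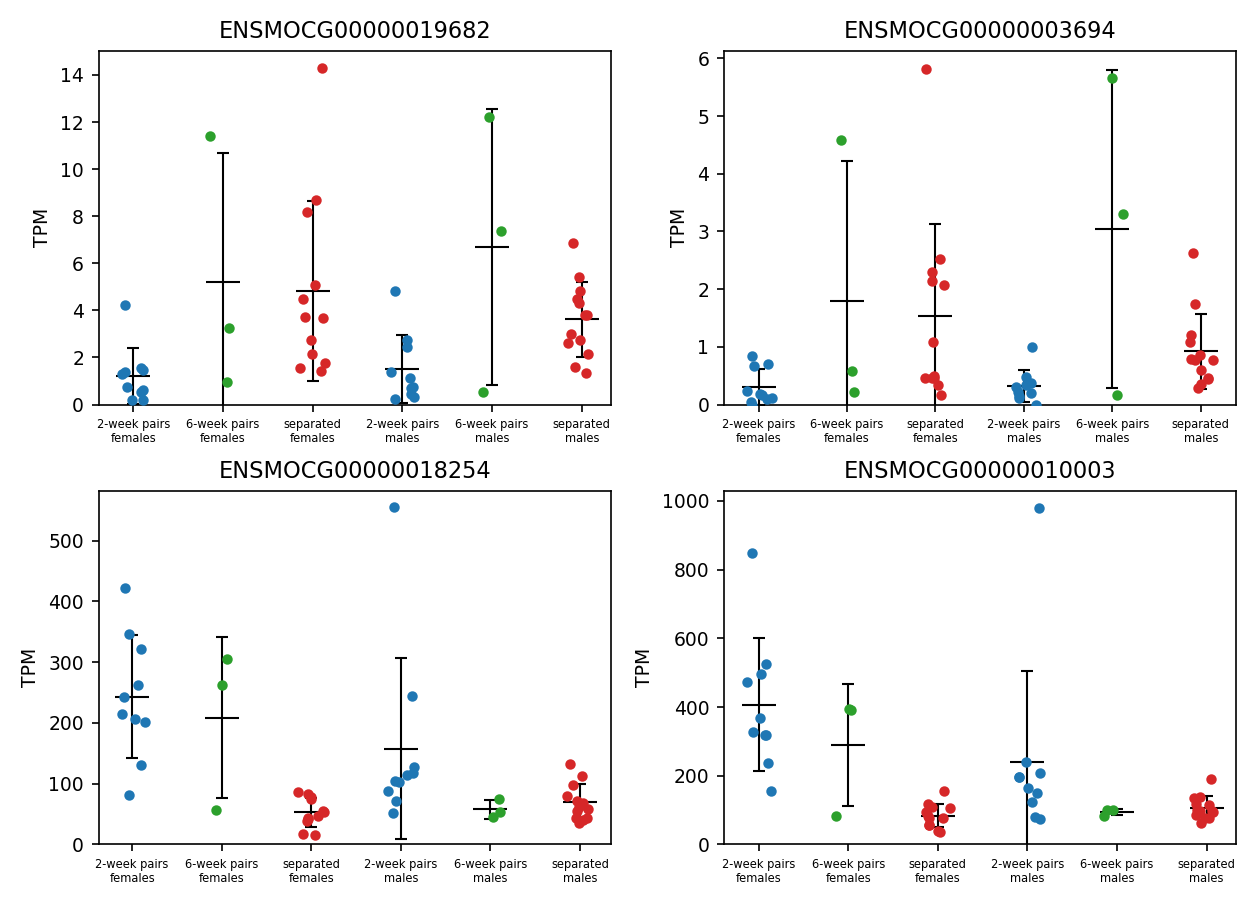
TPM of 4 genes in each library (points), by treatment and sex, with the group mean and SD (bars, which end at the axis where the SD exceeds the mean). ENSMOCG00000018254 averaged 243 TPM in 2-week paired females and 52.7 TPM in separated females, and 1 male of the 2-week pairs lay far above the other males in both lower panels.

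In females alone, 54 genes passed the threshold with limma, 19 higher and 35 lower after separation. The 4 genes named above were also the ones with the largest changes among those past the threshold with at least 100 normalized counts. ENSMOCG00000018254 and ENSMOCG00000010003 fell by 2.14 ± 0.35 and 2.13 ± 0.34 on the log2 scale (SE; limma adjusted p = 0.000842 for each). ENSMOCG00000003694 and ENSMOCG00000019682 rose by 2.09 ± 0.47 (limma adjusted p = 0.035) and 2.04 ± 0.42 (limma adjusted p = 0.0202). With the pair as a replicate block 7 genes passed, all 7 lower, among them ENSMOCG00000018254 (limma adjusted p = 0.00353) and ENSMOCG00000010003 (limma adjusted p = 0.00263). The higher genes ENSMOCG00000003694 (0.0724) and ENSMOCG00000019682 (0.0792) did not pass in it. Their calls were also lost without single females, at log2 fold changes of at least 1.73. For ENSMOCG00000019682 these were 2-week females 12 (0.0634), 13 (0.0501) and 14 (0.0648). For ENSMOCG00000003694 they were 2-week females 12 (0.0817), 13 (0.0759), 14 (0.0862) and 16 (0.0817) and separated females 17 (0.0518), 19 (0.0549), 25 (0.0784), 31 (0.0512) and 32 (0.0611). Over all alternatives the adjusted p ranged from 0.00173 to 0.604 for ENSMOCG00000003694 and from 0.00185 to 0.604 for ENSMOCG00000019682. For ENSMOCG00000018254 it ranged from 3.85e-06 to 0.299, and for ENSMOCG00000010003 from 3.65e-06 to 0.299. Quantile normalization left 19 genes (4 higher, 15 lower) and TPM values left 13 genes (3 higher, 10 lower). The count was 9 with array weights, 163 with DESeq2, 316 with the first principal component as a covariate and 124 with read total and fragment index as covariates. With cohorts averaged it was 9, and with 1 cohort left out it was 27 (cohort 1), 2 (cohort 2), 5 (cohort 3) and 4 (cohort 4). The 2 genes called without cohort 2 shared 0 with the 54. With 1 pair left out it lay between 7 and 86.

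In males, 0 genes passed with limma, and the smallest adjusted p was 0.0851. At an unadjusted p under 0.05 there were 1176 genes, against 708 expected by chance. Limma with array weights called 467 genes, 251 higher and 216 lower. On the recovered reads edgeR called 5 genes and DESeq2 called 22. Limma called 20 genes with the first principal component as a covariate and 32 with read total and fragment index as covariates. With limma 6 genes passed without pair 2, 3 without pair 13 and 10 without pair 17. The fold changes of the named genes in males were 1.61 for ENSMOCG00000019682, 1.49 for ENSMOCG00000003694, -0.77 for ENSMOCG00000018254 and -0.76 for ENSMOCG00000010003 on the log2 scale. The changes of the last 2 genes did not pass (limma adjusted p = 0.551 and 0.542), and without the 2-week male of replicate 11 they were -0.50 and -0.46 (0.767 and 0.776). Whether the effect differed between the sexes was tested as an interaction. For ENSMOCG00000018254 the male effect minus the female effect was 1.37 ± 0.50 on the log2 scale (SE; limma adjusted p = 1), and for ENSMOCG00000010003 it was 1.38 ± 0.49 (SE; limma adjusted p = 1). Without the male of replicate 11 these were 1.64 and 1.68 (limma adjusted p = 1 for each).

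The interaction called 1 gene, ENSMOCG00000017273 (log2 difference 5.40 ± 0.64, SE; limma adjusted p = 2.4e-06). It had 69.2 ± 59.4 normalized counts in 2-week paired females (SD, n = 9), ranging from 1.04 to 177.9. No read was recovered for it in the 12 separated females or in the males of the normalized table. Against a floor of 3 reads over all separated females, or 0.257 normalized counts, it was at least 269-fold lower in separated females. This floor covers counting error only. In the TPM table it was above 0 in 10 of 10 2-week paired females and 3 of 3 6-week paired females, and listed at 0 in 12 separated females and 26 males. In cohorts 3 and 4 the 6-week paired females lay between 1.14 and 3.14 TPM, above each separated female (two-sided exact permutation p = 0.0022, the smallest that the 455 splits allow). These splits exchange labels across the cohorts, so they do not hold cohort fixed. The gene had also been chosen in part on these separated females, which can make this p too small. The interaction call on this gene was lost without cohort 4 (limma adjusted p = 0.0652) and with edgeR (adjusted p = 1). Over its alternatives the adjusted p ranged from 8.44e-10 to 1.

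**Figure D2:**
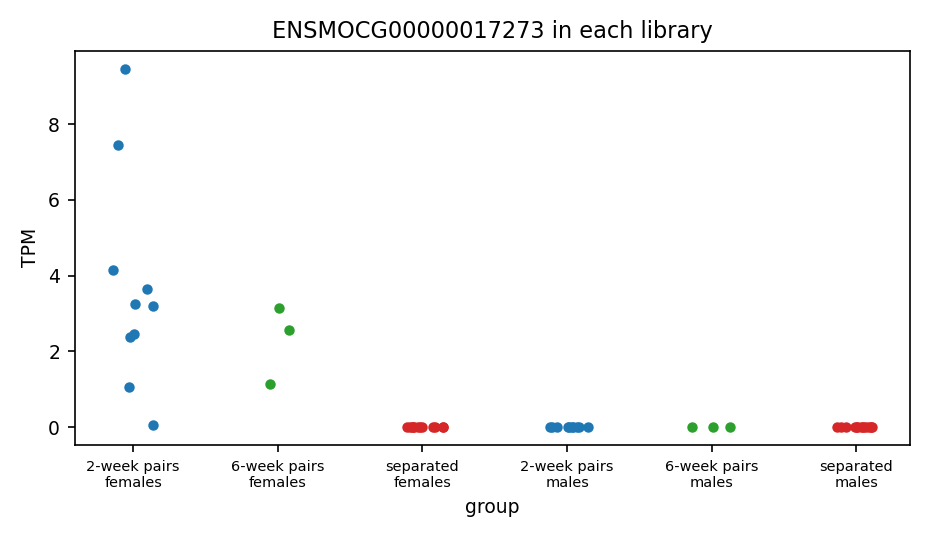
TPM of ENSMOCG00000017273 in each library (points), by treatment and sex. It was above 0 in all 10 females paired for 2 weeks, from 0.06 to 9.47 TPM, and in all 3 females paired for 6 weeks, and was listed at 0 in the separated females and in the males.

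The sexes were compared within each treatment. ENSMOCG00000017535 was lower in males of the 2-week pairs, with 669 ± 141 normalized counts against 1076 ± 120 in females (SD, n = 9 each; log2 fold change -0.70, limma adjusted p = 2.83e-05). It was lower in separated males too, with 859 ± 104 against 1203 ± 130 in females (SD, n = 12 each; log2 fold change -0.49, limma adjusted p = 0.00355). ENSMOCG00000012222 had 2129 ± 169 normalized counts in separated males and 2917 ± 205 in separated females (SD, n = 12 each; log2 fold change -0.45, limma adjusted p = 1.01e-06). Its log2 fold change in 2-week pairs was -0.41 (limma adjusted p = 0.000123). In 2-week pairs 3 genes passed, all lower in males, namely these 2 and ENSMOCG00000017273. In separated voles 3 genes passed, all lower in males; ENSMOCG00000014170 was the other gene there (log2 fold change -0.26, limma adjusted p = 0.0362). With TPM values 1 gene passed in each treatment, and it was none of these.

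Cohorts of one treatment were compared as a background. Cohort 2 differed from cohort 1 within the 2-week pairs in 1 gene, ENSMOCG00000013559 (log2 fold change 1.80 ± 0.31, SE; limma adjusted p = 0.0185), with 1384 genes at an unadjusted p under 0.05 against 708 expected by chance. That number was 293 with the first principal component as a covariate and 306 with read total and fragment index as covariates. Partners fall in the same cohort and were fitted as independent here, so 708 is not exactly the number to expect without a difference. ENSMOCG00000013559 lost its call in 7 alternatives, edgeR among them (edgeR adjusted p = 0.0869), with a range from 0.00132 to 0.486 over the alternatives. Cohort 4 differed from cohort 3 within separated voles in 0 genes with limma. At an unadjusted p under 0.05 there were 393, also against 708 expected by chance. There edgeR called 1 gene, DESeq2 called 3 and limma with array weights called 8.

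Separated voles were then compared with voles that stayed with their partner for 6 weeks, within cohorts 3 and 4. The groups are matched in time since pairing only if separation lasted 4 weeks, as the treatment label and the series design give it. The treatment protocol in the labels gives no interval between separation and sampling. With limma 0 of 13110 genes passed (2 with no filter on low values). At an unadjusted p under 0.05 there were 107 genes, against 656 expected by chance. Fewer genes than expected by chance fell below it, so the 0 is weak evidence that no genes differ. Of the 4 genes named for separation, ENSMOCG00000018254 averaged 208 ± 133 TPM in 6-week paired females (SD, n = 3) and 52.7 ± 23.8 TPM in separated females (SD, n = 12; two-sided exact permutation p = 0.011, adjusted over 8 comparisons 0.0527). Of the 6-week females 3 lay above the separated mean, the lowest at 57.2 TPM. ENSMOCG00000010003 averaged 290 ± 179 TPM and 84.3 ± 34.9 TPM in the same groups (two-sided exact permutation p = 0.0132, adjusted 0.0527), and 2 of 3 lay above the separated mean. Neither passed after adjustment. In males the 6-week and separated means of ENSMOCG00000018254 were 57.9 ± 15.8 (SD, n = 3) and 69.2 ± 29.5 TPM (SD, n = 13). ENSMOCG00000019682 averaged 5.22 ± 5.52 TPM in 6-week paired females (SD, n = 3) and 4.82 ± 3.84 TPM in separated females (SD, n = 12, two-sided exact permutation p = 0.866). Its 6-week female mean rests on pair 18, at 11.4 TPM. The females of pairs 27 and 22, at 3.27 and 0.938 TPM, lay below the separated mean. These per-gene tests were chosen after the values were seen. Between 6-week and 2-week pairs 0 of 13141 genes passed with limma (3 with no filter on low values). There 242 had an unadjusted p under 0.05, against 657 expected by chance, so this 0 is weak evidence too. No read counts were available for 6-week pairs, so no count-based tool was run in these comparisons.

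Partners were compared with non-partners of the same cohort. The mean correlation across genes was 0.211 ± 0.218 for 2-week partners (SD, n = 9 pairs) and, averaged per pair, -0.045 for non-partners. The tested excess, which gives each non-partner combination the same weight, was 0.254 (one-sided exact permutation p = 0.00526 over 10080 reassignments). Cohort 1 holds 2 pairs, and subtraction of its means gives both the same partner correlation (0.055), so they are not independent. Without cohort 1 the excess was 0.298 (one-sided exact permutation p = 0.00813, 7 pairs). In separated voles partners correlated at 0.282 ± 0.235 (SD, n = 12 pairs) and non-partners at -0.055 averaged per pair. The tested excess was 0.335 (one-sided permutation p = 3.00e-05). The excess averaged per pair did not differ detectably between treatments (separated minus 2-week 0.081, two-sided permutation p = 0.525), a contrast that cannot be told apart from cohort.

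The similarity went with the first principal component, which held 33.5% of the variance. Over 21 pairs the PC1 scores of female and male partners had a Pearson r of 0.947 and a Spearman rho of 0.895 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give; adjusted over 9 measures 9.00e-05). Without the 2 pairs farthest from the female median r was 0.925. Within cohorts it was 0.968 in cohort 2 (7 pairs) and 0.935 in cohort 4 (7 pairs), and cohorts 1 and 3 held fewer than 6 pairs. For the partner excess the component removed was instead the first of the values centred on cohort and sex. After its removal the excess was -0.09 in 2-week pairs (one-sided exact permutation p = 0.853) and -0.008 in separated pairs (one-sided permutation p = 0.546). PC1 also followed the read total of the library (Pearson r = -0.795, Spearman rho = -0.794, permutation p = 1e-05 for each, n = 42) and the fragment index (Pearson r = -0.737, Spearman rho = -0.708, permutation p = 1e-05 for each, n = 42). It moved with the share of counts in the 11 most abundant IDs too (Pearson r = 0.628, permutation p = 1e-05; Spearman rho = 0.611, permutation p = 4.00e-05; n = 42). The adjusted p over these 3 measures was 1e-05 for each. Without the 2 farthest libraries the r values were -0.78, -0.677 and 0.579. Within cohorts r for the read total was -0.918 in cohort 2 (n = 14), -0.678 in cohort 3 (n = 10) and -0.782 in cohort 4 (n = 14), for the fragment index it was -0.798, -0.718 and -0.712, and for the share of the 11 IDs it was 0.451, 0.808 and 0.697. Cohort 1 held too few libraries (n = 4). Partners are counted as separate libraries in these values, which makes their p too small where partners are alike. Partners shared their read totals as well (Pearson r = 0.664 on the log2 scale, permutation p = 9.10e-04; Spearman rho = 0.734, permutation p = 2.80e-04; 21 pairs; adjusted over 9 measures 0.00409). Without the 2 farthest pairs this r was 0.681, and it was 0.785 in cohort 2 and 0.79 in cohort 4 (7 pairs each). Treatment accounted for a share of 0.024 of the variance of PC1 and sex for 0.

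**Figure D3:**
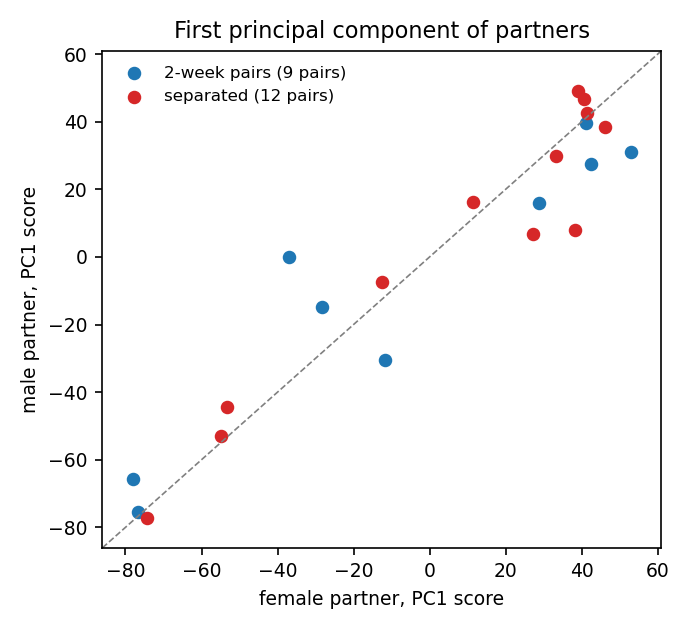
PC1 score of the female (x axis) and the male (y axis) of each of 21 pairs, in units of the component, coloured by treatment; the dashed line marks equal scores. The points lie along the line in both treatments (Pearson r = 0.947).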

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

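The tests of current cohabitation, of the share of the most abundant IDs, of the first principal component as a covariate, and of cohort and depth for ENSMOCG00000017273 were chosen after the results were seen. Of 27 groups of values examined for a library or pair far from the rest, 5 stood out. About 1 in 20, or 1.4, would do so for independent, normally distributed values. The counts were not put on a log scale here, and the 2-week male of replicate 11 was flagged for both ENSMOCG00000010003 and ENSMOCG00000018254. No excess of outliers is therefore shown.

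The normalized count of ENSMOCG00000019682 in the 2-week female of replicate 10 was 487, and the next highest of the 9 was 172.8. The 2-week male of replicate 9 had 103 normalized counts of ENSMOCG00000003694, against 59.47 in the next. The 2-week male of replicate 11 had 9613 normalized counts of ENSMOCG00000010003 and 2837 of ENSMOCG00000018254, while the next highest males had 3091 and 698.1. Partners of pair 9 correlated at 0.76 across genes, and the next highest 2-week pair at 0.241.

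ENSMOCG00000017273 had a difference of 5.40 on the log2 scale in the interaction test. No read was recovered for it in males of either treatment, so a fall could be seen in females only. The test therefore cannot show that males respond otherwise than females. None of the other 99 exchanges of the sexes within pairs called a gene (1 of 100 splits, highest other 0). Such exchanges also undo a plain sex difference, so a gene read in females only would tend to exceed them. They therefore do not exclude chance for the interaction itself. A cohort batch would leave the gene at 0 in the 6-week females, who share cohorts 3 and 4 with the separated females. The gene was above 0 in 3 of 3 6-week females and in 0 of 12 separated females, which argues against such a batch. The exact permutation p of 0.0022 comes from splits that mix these cohorts. Low depth in separated females is also argued against, since 10 of 12 had a read total at or above the lowest of the 2-week females, 22324420 reads. Whether the presence of a male or a state that follows from it accounts for the gene stays open and untested, as the labels give no such state.

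Partners shared the first principal component whether or not they still lived together. Current cohabitation is argued against as its only source, because separated pairs still had a partner excess of 0.335, against 0.254 in 2-week pairs. The difference averaged per pair was 0.081 (two-sided permutation p = 0.525) and cannot be told apart from cohort. Whether cohabitation adds to the likeness of 2-week pairs therefore stays open. A trend with gene length in each library is argued against too, since 0.98 of the excess was left after its removal, while the share of counts in the 11 most abundant IDs stays open: regression of PC1 on it left a partner r of 0.526 (permutation p = 0.0139), past the bound of 0.5 written before that value was seen, but 0.42 without the 2 farthest pairs, and that this was too close to exclude it was decided after both were seen. After regression of PC1 on read total and fragment index the partner r fell from 0.947 to 0.288 (permutation p = 0.206, 21 pairs), which is consistent with library depth and fragment length carrying most of the likeness, though 0.288 lies close to the bound of 0.3 set in advance and r was 0.411 without the 2 farthest pairs. Why partners had like read totals was not tested, as the labels give no order of dissection or library preparation, and a shared biological state of a pair stays open.

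Few splits gave as many genes as the 465 that differed between separated and 2-week paired voles. Of 100 splits that keep partners together 3 did so, the real one included. The highest other split gave 2188, which points to a structure of the libraries. With the pair as a replicate block the real split gave 8 genes and the highest other 1 (1 of 100 as large, the real one included). The partner correlation of the real grouping was kept in that fit. These shares were not adjusted over the comparisons, so they do not exclude chance. With the first principal component as a covariate all 465 remained past the threshold with the same sign. Treatment accounted for a share of only 0.024 of the variance of that component, so this was likely in advance and decides little. In that fit the highest other of those splits gave 10 genes against 1246, which argues against the first principal component alone as the source of the count. Other structure of the libraries was not tested. Cohort or time since pairing could not be excluded. Pairs were placed on 200 genes chosen in one set of pairs and scored in others, where 2-week pairs average 0 and separated pairs 1. The 6-week pairs lay at 0.79 (pair 18), 1.89 (pair 27) and -0.21 (pair 22). After the first principal component of the TPM values, which was fitted on all pairs and not held out, they lay at 1.26, 1.39 and -0.23. As deposited pair 27 lay above the separated range (-0.36 to 1.83), pair 22 lay within both ranges, and the shift that sets the scale was below 0 in at least 1 halving of the pairs (lowest -0.353), so these positions place no pair firmly, and 3 pairs are too few to say which position is typical.

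For the other counts of genes, few splits gave as many in females (54 genes, 2 of 100 splits with the real one included, highest other 4670). Few did so for the sex difference in 2-week pairs (3 genes, 2 of 100, highest other 5) and separated voles (3 genes, 1 of 100, highest other 2). These shares were not adjusted over the comparisons, so they do not exclude chance. The count for cohort 2 against cohort 1 did not stand out from its splits (1 gene, 10 of 36, highest other 5932). A count of 0 is matched by any split (100 of 100), so for such counts the comparison decides nothing. The highest other count was 3827 in males and 4712 for cohort 4 against cohort 3. It was 6643 for separation against 6-week pairing and 5721 for 6-week against 2-week pairing. The splits that called many genes again point to a structure of the libraries.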

How the results depend on the processing

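Settings with the first principal component as a covariate, with read total and fragment index, without single pairs or libraries, and the TPM table without the 3 left-out libraries were chosen after seeing the data; the cause of a change was not tested unless stated. Counts are given for separation with sexes averaged (465), females (54), males (0) and the interaction (1), in that order where several follow. The replicate block gave 8 and 7 for sexes averaged and females, and left the counts in males, for the interaction, for sex and against 6-week pairs as they were; it was not run for the cohort comparisons. Array weights gave 1898, 9 and 467, and 8 for cohort 4 against 3. The TPM table gave 39 and 13, with 0 for the interaction, 1 for each sex comparison and 0 for cohort 2 against 1. Without the 3 left-out libraries it gave 51, 11, 0, 1 and 0, so those libraries do not account for the lower counts. The TPM table moved the median of all genes in females to -0.126 on the log2 scale, for the interaction to 0.104 and for cohort 2 against 1 to -0.162. Quantile normalization gave 19 in females and 0 for cohort 2 against 1. On recovered reads edgeR gave 5 in males, 0 for cohort 2 against 1 and 1 for cohort 4 against 3. Its interaction count of 1 shared 0 genes with limma. DESeq2 gave 163, 22 and 2 for females, males and the interaction, 11 for cohort 2 against 1 and 3 for cohort 4 against 3. The mean of at least 50 removed the only gene of the interaction (0) and of cohort 2 against 1 (0). No filter gave 2 for the interaction, 5 for sex in 2-week pairs, 8 for cohort 2 against 1, 2 for separation against 6-week pairing and 3 for 6-week against 2-week pairing. Cohorts averaged gave 9 in females. Without cohort 1 the counts were 253 and 27. Without cohort 2, with fewer libraries, they were 11, 2, 2 and 0. Without cohort 3 they were 5, 8 and 3 for females, males and the interaction, and without cohort 4 they were 7 and 4 with 0 for the interaction. The first principal component as a covariate gave 1246, 316 and 20, with the replicate block 1163, 314 and 20, and read total and fragment index gave 861, 124 and 32. Both covariate fits gave 0 for cohort 2 against 1.

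Leaving out a pair gave 236 to 809 with sexes averaged, 7 to 86 in females and 0 to 10 in males. With sexes averaged the count moved by over 1.5 times without pair 8 (288), 16 (236), 17 (809), 25 (269), 29 (308) and 30 (305). In females it rose without pairs 8 (85), 10 (86) and 11 (82). It fell to 7 without pair 13 or 16, to 10 without 14, to 13 without 25 or 32, to 17 without 2, 12 or 30, to 18 without 21, to 19 without 19, to 20 without 9, to 23 without 28, to 28 without 31, to 32 without 29 and to 33 without 24. In males it rose without pairs 2 (6), 13 (3) and 17 (10). The 6-week against 2-week count was 0 to 1 without single 6-week libraries, with 1 without the male of pair 18.

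After the first principal component of the centred values the partner excess was -0.09 in 2-week pairs and -0.008 in separated pairs. After read total and fragment index it was -0.069 and 0.038. It stayed past the threshold in the other settings run, and separated minus 2-week stayed positive and short of it. Of 411 values of named genes under alternatives, 343 kept their call and direction, 68 lost the call and 0 reversed; single libraries are counted there only where they changed a call or moved an effect by over 1.5 times. Leaving out single libraries moved the effect in males by over 1.5 times for ENSMOCG00000018254 (-0.50) and ENSMOCG00000010003 (-0.46), both without the 2-week male of replicate 11. It moved the interaction, short of the threshold throughout, for ENSMOCG00000019682 (main -0.43) without 2-week males 2 (-0.26), 8 (-0.69), 9 (-0.21) and 14 (-0.25) and females 10 (-0.68) and 12 (-0.11), and for ENSMOCG00000003694 (main -0.60) without female 12 (-0.32). The planned gene list tests and the adjustment for cell make-up were not run, since no ID matched a gene name. Depth limits genes with few reads, and the 6-week libraries have no recovered reads.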

Other observations

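The comparisons after the first principal component, and those of single genes with 6-week pairs, were chosen after the results were seen. After the first principal component the 9 2-week pairs lay between -0.37 and 0.49 on the held-out separation genes and the 12 separated pairs between 0.74 and 1.64. The scale was set by these groups, so only the gap between them and the place of the 6-week pairs are measured. The component was that of the TPM values, and its removal was fitted on all of these pairs with their treatment labels. Only the choice of genes was thus held out, which may widen the gap. On this scale 6-week pairs 18 and 27 lay within the separated range (1.26 and 1.39) and pair 22 within the 2-week range (-0.23). The held-out shift that sets the scale was 0.236 to 0.539 on the log2 scale over 100 halvings. Before the component was removed the ranges overlapped, from -0.77 to 0.72 and from -0.36 to 1.83, and the shift ran from -0.353 to 0.477. ENSMOCG00000017273 did not follow this scale: it was above 0 TPM in the females of all 3 6-week pairs, while 1 of those pairs lay in the 2-week range and 2 in the separated range.

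The means of ENSMOCG00000018254 and ENSMOCG00000010003, which were lower after separation, were 243 and 407 TPM in 2-week paired females, 208 and 290 in 6-week paired females, and 52.7 and 84.3 in separated females. In 6-week paired males the means were 57.9 and 94.5 TPM. The difference between 6-week and separated females missed the threshold after adjustment for both genes (exact permutation, adjusted p = 0.0527). Both had been named for low values in these same separated voles, a choice that favours a higher 6-week mean. The 2 genes that were higher after separation had 6-week means above the separated ones in both sexes, and none of these differences passed. For both genes and in both sexes pair 18 had the highest 6-week value and pair 22 the lowest. The female means rest largely on pair 18. In males pair 27 also lay above the separated mean, at 7.36 TPM of ENSMOCG00000019682 and 3.3 TPM of ENSMOCG00000003694. For each gene 1 of 3 6-week females and 2 of 3 6-week males lay above the separated mean. ENSMOCG00000003694 averaged 1.8 TPM in 6-week and 1.53 in separated females (two-sided exact permutation p = 0.971), and 3.04 and 0.921 in males (two-sided exact permutation p = 0.0857, adjusted 0.229). In pairs 18, 27 and 22 the 6-week females had 4.59, 0.59 and 0.215 TPM of it, and the males 5.66, 3.3 and 0.173 TPM. ENSMOCG00000019682 averaged 5.22 and 4.82 TPM in females (p = 0.866), and 6.7 and 3.62 in males (p = 0.625). The log2 difference had the opposite sign in females for both, at -0.02 and -0.11.

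The female and male effects of separation had a Pearson r of 0.445 across 14151 genes, which are not independent replicates, with a covariance of 0.043 against a median of 0.00871 over the other splits. Among 100 splits that keep partners together 16 gave as high a correlation, the real one included, so by the bound set in advance (0.05 of splits) library variation shared by partners was not excluded as its source. With the first principal component as a covariate r was 0.378, and 1 of 100 splits gave as high a value (highest other 0.243). That the answer was left open was decided after both values were seen.

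The 3 libraries outside 6-week pairs that the authors left out of the normalized table, the female and male of pair 15 and the male of pair 23, stood apart in the TPM table. The 11 most abundant IDs held 9.82% to 12.42% of their TPM, and 23.01% to 48.65% in the other 48 libraries. On the second principal component of the TPM table, which held 15.7% of the variance, they scored 111.2, 95.7 and 107.5, and the others between -25.6 and 16.3.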
